A study of Mus musculus with 6 samples.

How the data were processed

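Gene expression was measured in whole mouse testis 10 days after a single exposure of the scrotum to 43 degrees C for 20 min. The samples were 3 testes of C57BL/6 mice (B6) and 3 of B6.MRLc1 mice, all 3 months old per the labels. B6.MRLc1 is a congenic strain that carries a segment of chromosome 1 from MRL mice on the B6 background, between 67.97 and 81.63 cM per the labels. The series' design text counts 3 mice of each strain, and each array was taken as 1 mouse. Arrays of unheated testes were not analysed here, so no value below is a response to heat.

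Per the labels' protocols, the authors purified total RNA on columns, labelled 0.1 ug of it with Cy3 by a low-input kit and hybridised each sample to a one-colour Agilent array. The deposited scanner tables hold linear intensity values per spot, and per the file headers the processed intensity is background-subtracted and spatially detrended, with a surrogate value for spots near background. These intensities were not scaled between arrays. Per the file headers the deposited tables also hold flags of 0 or 1 for spots that are well above background, saturated or outliers. The file headers name Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5.3, and which of these made the values is not known. All 6 arrays lay on 1 slide and came from 1 scan. The B6 arrays occupied slide row 1 and the B6.MRLc1 arrays slide row 2, so slide row and strain cannot be told apart by any fit. In both strains the replicate number, 1 to 3, was also the slide column.

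The deposited table of processed values for the whole series holds log2 values whose making is not given in the sources used here. Set against the scanner signals, at least 99.9% of its values for probes filled on all 6 arrays lay within 0.05 of the log2 scaled signal minus the probe's median over the arrays. Its column medians were -0.003, -0.00405, 0.0144, 0.00474, 0.00986 and 0.0161 for B6 arrays 1 to 3 and then B6.MRLc1 arrays 1 to 3. A cell was filled in at most 0.14% of cases where the spot was not well above background.

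Here, control spots and spots flagged as non-uniform or population outliers were left out, each array was divided by the 75th percentile of its processed signal, and log2 was taken. Spots of one probe were averaged. A probe was kept when it had values on at least 4 arrays and more than 0.5 of its spots were well above background on at least 3 of the 6 arrays. This left 36627 of 55681 probes. For each gene the probe with the highest mean over the 6 arrays was tested, which gave 25276 genes. Gene names came from the RefSeq accession on the array through a table of assembly GRCm38.p6 for 27235 probes, from the file's own symbol where that table holds it for 3581 probes, and from the file alone for 24865 probes. Positions are those of the array annotation, and the file headers name genome build mm9 (NCBI37). No position was taken from the GRCm38.p6 table, and exons and untranslated regions were not analysed here.

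Strains were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All fold changes are B6.MRLc1 relative to B6 on the log2 scale, with the standard error of the fit. Levels are means of log2 signal relative to the array's 75th percentile. Where no probe of a gene was well above background on any array of a group, the brighter group is given as at least N-fold higher. That bound sets the bright group's mean against the mean of, per array, the higher of the dim probe's own value and the lowest signal well above background. It holds for the scale of the processed signal only, and normexp, whose offset of 50 draws dim values together, gives smaller differences. The chromosome 1 segment was represented by the span from the first to the last gene of a list of known interval genes, leaving out listed genes placed more than 20 Mb from the median position. Called and other genes inside and outside that span were compared by a two-sided Fisher's exact test. In total, 23 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Their p-values are for a shift of the list in 1 direction, unless fry for change in either direction is named. A list's score on an array is the median over its genes of the log2 signal minus each gene's mean over the 6 arrays. The adipocyte and epididymis lists held markers of carry-over of these tissues, and the red cell list held markers of blood.

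The samples' groups, the tests, the gene lists and the processing alternatives were fixed before the data were examined. So was the rule for the genes named. It takes the 12 largest fitted changes in each direction among called genes with a symbol (clone, model and accession names do not count), after the 10 called genes of the interval span with the smallest adjusted p. It adds up to 4 members with the smallest p of each list called by camera and of the mineralization list, together with Spp1, Mgp, Alpl and Enpp1. The minimum of 4 values, the 0.5 of spots and the 20 Mb limit were not among the settings fixed then. Some genes that the rule takes are not reported here. Other genes named below were chosen after their values were seen. The alternatives changed the background correction, the scaling, the filter on dim probes, a floor, the outlier spots, the source of the values, the variance model, array weights, the replicates used, the probe per gene, the span and the set test. An alternative without 2 of the arrays was added after the data were seen. Slide and scan could not serve as blocks, since each had 1 level.

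The fit was tested on simulated data for the 25271 genes with complete values, using the spread between arrays of a strain. There were 200 changed genes, and a further list of genes was shifted as a group. Noise was drawn independently for each gene, so deviations shared by many genes of an array were not simulated. The fit recovered 77% of the genes planted with a 2-fold change and 91% of those planted with a 4-fold change. Of its calls there 6.37% were false, and these shares may not hold for the real arrays. The number of arrays limits the precision of every value.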

Results

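The data are 6 one-colour arrays of heat-exposed testis, 3 from B6 mice and 3 from B6.MRLc1 mice. The study's stated subject is the onset of calcification in the testis after heat, and the comparison asks which testis genes differ between the strains at day 10. The share of spots well above background was 68.6%, 69.0% and 68.7% on B6 arrays 1, 2 and 3. It was 58.0%, 62.2% and 64.7% on the corresponding B6.MRLc1 arrays, which lay in the other row of the slide. The 75th percentile of the processed signal ran from 556.8 to 669.8 intensity units, and no spot was saturated. The first principal component held 54.1% of the variance. Correlations of log2 signal across genes were 0.991 to 0.995 within a strain and 0.979 to 0.990 between strains, and genes are not independent replicates.

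Most genes that differed were lower in B6.MRLc1 testes. Rnf151, a RING finger gene of the acrosome, fell by 3.44 on the log2 scale (SE 0.53), from -0.72 ± 0.55 in B6 to -4.16 ± 0.96 in B6.MRLc1 (SD, n = 3; limma adjusted p = 0.0408). Adam3, which sperm need to bind the egg coat, and Gk2, a testis glycerol kinase, fell by 3.28 and 3.42 (adjusted p = 0.0497 and 0.0266). Both were well above background on only 1 B6.MRLc1 array, and the other Adam3 probe read -1.93. With normexp background correction Rnf151, Adam3 and Gk2 measured -2.15, -1.86 and -1.22. Among higher genes, Col6a4, a collagen VI chain, rose 3.94-fold, by 1.98 on the log2 scale (SE 0.11, n = 3 per strain; limma adjusted p = 0.00622), and measured 0.89 with normexp.

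In total, 664 of 25276 genes were called, 102 higher and 562 lower in B6.MRLc1, and 5122 genes had an unadjusted p under 0.05. Of the called genes, 15 had a fitted change at least 2-fold higher and 322 at least 2-fold lower. Of them 142 were not well above background on any B6.MRLc1 array, and 3 on any B6 array. The scanner's estimate of additive error was 2.66 to 3.14 on B6 arrays and 3.38 to 5.68 on B6.MRLc1 arrays. A dim signal that passes as well above background in B6 may thus not pass in B6.MRLc1, so not passing does not show lost expression. Beside 10 interval genes, the naming rule on fitted values took the lower genes Slc6a21, Tmbim7, Rnf133, Rnf151, Gk2, Kcnmb4os1, Pmfbp1, Spata45, Znrf4, Prss55, Cstl1 and Adam3, whose order cannot be measured because B6.MRLc1 was near background. For Rnf133, Spata45 and Cstl1 no B6.MRLc1 array was well above background, and B6 was at least 4.34-fold, 3.43-fold and 3.08-fold higher on the scale of the processed signal. With normexp these genes measured only -1.09, -0.84 and -0.87 on the log2 scale, and Cstl1 lost its call (adjusted p = 0.062). Of the other 9, Rnf151 was well above background on 2 B6.MRLc1 arrays and the remaining genes on 1, and with normexp all of these measured -2.15 to -0.89. The higher genes it took included Ifi202b, Ltb4r2, Col6a4, Orm1, Olig1, Inpp5j, Klhl30, Rgs7, Hrk, Tulp1 and Ncbp3. Ltb4r2, a leukotriene B4 receptor, was not well above background on any B6 array and was at least 4.2-fold higher in B6.MRLc1 on that scale, but measured 0.83 with normexp. Orm1, an acute phase protein gene, rose by 1.96 (1.00 with normexp) and Hrk, a cell death activator, by 1.07 (adjusted p = 0.0409 and 0.0228). The number of called genes was 50 without B6 array 1, 169 without B6 array 2, 83, 58 and 318 without B6.MRLc1 arrays 1, 2 and 3. Only 27 genes were called in all 6 fits that left out 1 array, among them Col6a4, Dusp23 and Fmo1, and 9 of the 52 called genes named by the fixed rule. Without the filter on dim probes 50 genes were called, with the deposited series values 440, with a variance trend 1202, with array weights 1607, and with normexp 273 higher and 612 lower. With the replicate number, which was also the slide column, as a block, 0 genes were called by limma.

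Genes of the MRL chromosome segment differed more often than genes elsewhere, and in both directions. Dusp23, a phosphatase gene at chromosome 1, 174560901 to 174560960 (mm9 probe position), fell 4.73-fold, from 0.08 ± 0.11 to -2.16 ± 0.08 (SD, n = 3; adjusted p = 0.00305). Fmo1, a flavin monooxygenase at 164760037 to 164760096, rose 2.84-fold from -1.34 ± 0.06 to 0.16 ± 0.12 (SD, n = 3; adjusted p = 0.00609). Spata46, a gene of spermatid nuclear shape at 172242182 to 172242241, was well above background on 3 B6 arrays and on 0 of the B6.MRLc1 arrays. It was at least 9.43-fold higher in B6 on the scale of the processed signal (adjusted p = 0.0117), but measured -1.73 on the log2 scale with normexp. Ifi202b, an interferon-inducible gene at 175892789 to 175892848, read -0.18 ± 0.06 in B6.MRLc1 and -6.75 ± 1.60 in B6 (SD, n = 3), where 1 of 3 arrays was well above background (adjusted p = 0.0255), and the difference was 3.12 with normexp.

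The span of listed genes ran from 163170713 to 175893982 on chromosome 1. Inside it 28 of 169 tested genes were called, 12 higher and 16 lower, against 636 of 25107 elsewhere. The odds ratio was 7.64 (95% interval 4.86 to 11.6; Fisher's exact test, two-sided, p = 7.25e-15). It was 21.2 (10.4 to 40.0) for higher genes alone and 4.70 (2.60 to 7.96) for lower genes alone. Fisher's test counts each gene as independent, which near-identical genes of the span need not be. Its p-values may thus be too small and its intervals too narrow. The odds ratio was 25.2 without B6 array 1, 21.5 without B6.MRLc1 array 1, 24.9 without B6.MRLc1 array 2 and 27.6 without the filter on dim probes, with p at most 4.14e-08. In these fits only 7 to 10 genes of the span were called. It was 9.86 without B6 array 2, 11.2 without B6 array 3 and 6.19 without B6.MRLc1 array 3, with Fisher's exact p at most 1.67e-06. In the list of interval genes fixed beforehand, 11 tested members were higher, 13 lower and 83 not called over all genes tested. Adjusted over the list alone, 21 were higher and 25 lower. Among other called members, Ppox, of haem synthesis, fell by 1.01 and Klhdc9 by 0.71, while Pea15a rose by 0.73. Fcgr2b, the inhibitory Fc receptor gene, fell by 1.34 and Apoa2, an apolipoprotein gene, rose by 0.35 (1.29 on its other probe). An unnamed transcript probed at 173257355 to 173257414 rose by 1.26. Itln1, a lectin gene, was not well above background on any B6 array and was at least 4.26-fold higher in B6.MRLc1 on that scale, but measured 0.91 with normexp. Within 5 Mb beyond the end of the span lay Rgs7, which was higher (1.14, and 0.49 with normexp), and Exo1, which fell by 0.82 (adjusted p = 0.0247). Ifi202b, Ifi204 (-1.17), Ifi211 (-2.80, and -1.87 with normexp) and Itln1 belong to families of near-identical genes, so their signals are uncertain as to the member measured. The Nuf2 probes disagreed: the tested probe fell by 1.29 and a dimmer one measured 3.60, so no direction is given for Nuf2. The counts and the odds ratio of lower genes above include Nuf2 by its tested probe.

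**Figure D1:**
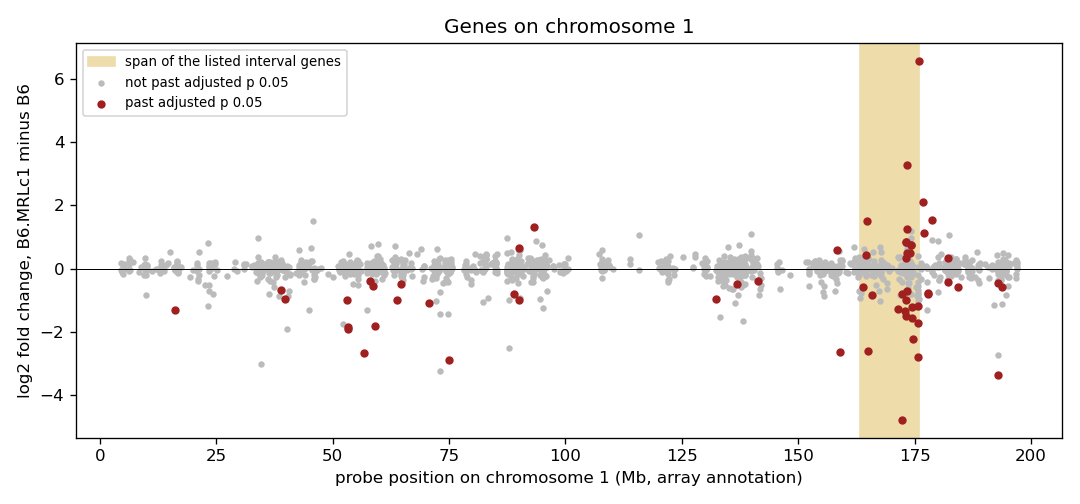
Log2 fold change (vertical axis) of each tested gene on chromosome 1 against its mm9 probe position in Mb (horizontal axis), 3 B6.MRLc1 against 3 B6 arrays. Dark red points are called genes, grey points are not, and the shaded span holds 28 called genes among 169.

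Genes of spermatids, the germ cells after meiosis, were lower as a group in B6.MRLc1 by camera at its preset correlation. That call was lost at adjusted p = 0.346 with an estimated correlation for round spermatids and at adjusted p = 0.728 with an estimated correlation for elongating spermatids. Of 30 tested genes of round spermatids and the acrosome, 11 fell and 0 rose, with a list median of -1.41 on the log2 scale. Of 39 genes of elongating spermatids, the sperm tail and the sperm nucleus, 8 fell and 0 rose, with a median of -1.88. Examples are Dkkl1, an acrosomal protein gene, which fell by 1.98, Acr, the acrosin gene, by 0.90 (-0.52 with normexp), Tcp11 by 1.82 (-0.15 on its other probe), and Odf4 of the sperm tail by 2.88 (-0.94 with normexp), with 1 B6.MRLc1 array well above background. Genes of the earlier germ cells had a median of -0.04 over 41 spermatocyte genes and of 0.11 over 25 spermatogonial genes.

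Adjusted over the list alone, 23 round and 34 elongating spermatid genes fell. Catsper1, a sperm calcium channel gene, and Cylc2, of the sperm head, were not well above background on any B6.MRLc1 array, and were at least 1.81-fold and 2.88-fold higher in B6 on the scale of the processed signal, but measured only -0.44 and -0.53 on the log2 scale with normexp. Spaca7, well above background on 1 B6.MRLc1 array, fell by 2.34 (-1.04 with normexp), Lyzl6 by 1.44 (-0.91), Tekt4 by 0.97 and Klhl10 by 0.90 (-0.59). The protamine and transition protein genes did not pass in the reported fit: Tnp2 measured -4.07 (SE 0.80; adjusted p = 0.0649) and Prm1 -3.55 (SE 0.73; adjusted p = 0.0696). With normexp they passed by limma, Tnp2 at -3.43 (adjusted p = 0.026) and Prm1 at -3.33 (0.0335). Tnp1 (-2.87, adjusted p = 0.0233), Prm3 (-2.13, 0.0214) and Prm2 (-1.98, 0.0488) passed there too. In the spermatocyte list 3 of 41 members fell, namely Ldhc, the testis lactate dehydrogenase gene, by 3.18, Rec8, a meiotic cohesin gene, by 0.52, and Nsun7 by 1.89, and 0 rose. Nsun7 was well above background on 2 B6.MRLc1 arrays, a second probe read 0.39, and with normexp Nsun7 measured -0.86. Adjusted over the list alone 5 fell, and Ybx2 measured -1.20 (adjusted p = 0.0526 over all genes). Camera gave adjusted p = 8.17e-16 for round spermatids, 6.79e-19 for elongating spermatids and 0.0187 for spermatocytes. The spermatocyte call was also lost, at adjusted p = 0.851 with an estimated correlation. Under fry the adjusted p was 0.0149 for round spermatids, and elongating spermatids (0.069) and spermatocytes (0.404) did not pass. Spermatogonial genes were not called (adjusted p = 0.634), although Dmrtb1 fell by 1.29. The spermatid medians moved to -0.49 and -0.69 with normexp background correction, to -1.12 and -1.53 with dim values raised to a floor at the lowest signal above background, and to -0.90 and -0.97 over genes well above background on all arrays. Both spermatid calls held without any 1 array, while the spermatocyte call was lost without B6 array 3 (adjusted p = 0.218) and without B6.MRLc1 array 1 (adjusted p = 0.3). The spermatocyte median was -0.06, -0.10 and -0.00275 without B6 arrays 1, 2 and 3, and 0.04 and -0.11 without B6.MRLc1 arrays 1 and 3.

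**Figure D2:**
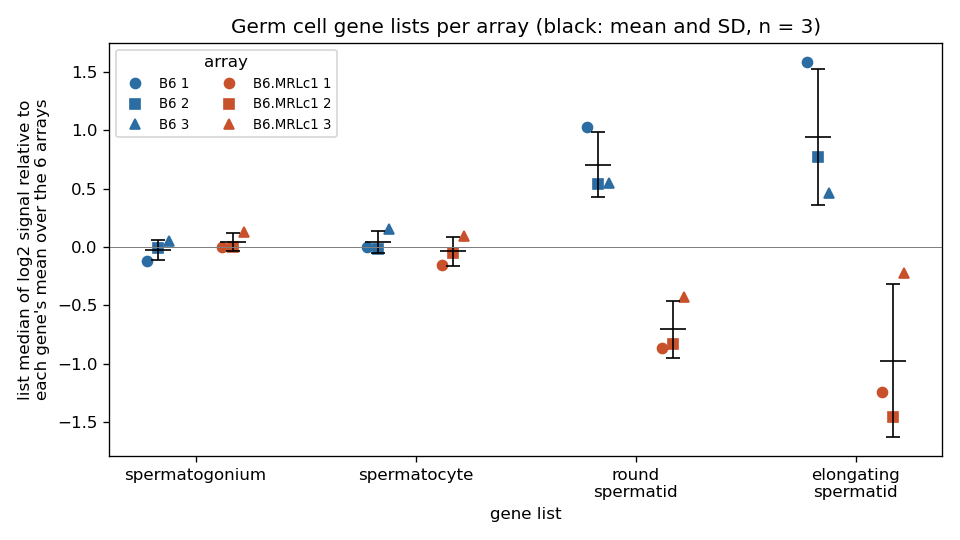
Score of each germ cell gene list (vertical axis, log2 units relative to each gene's mean over the 6 arrays) for every array, with the mean and SD of 3 arrays per strain in black. Round spermatid scores were 0.54 to 1.03 in B6 and -0.86 to -0.43 in B6.MRLc1.

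Camera at its preset correlation also called 9 lists of supporting, immune, fat and cell death genes. None of these calls held, at adjusted p = 0.346 with an estimated correlation for cell death and adjusted p = 0.851 with an estimated correlation for each of the others. Sertoli cell genes had a median of 0.09 over 29 members, peritubular myoid genes 0.13 over 12, extracellular matrix genes 0.15 over 42 and adipocyte genes 0.96 over 10. The adipocyte list was fixed as a marker of fat carried over with the testis, and whether carry-over differed was not tested. Medians below 0 were found for 14 endothelial genes (-0.12), 24 macrophage genes (-0.24), 30 inflammation genes (-0.28), 42 interferon response genes (-0.15) and 37 cell death and p53 genes (-0.09). Single members passed in only 3 of these lists. The cell death genes Bbc3 and Bik, both activators, and Birc5, an inhibitor, fell by 0.63, 1.28 and 0.57. Timp1, a protease inhibitor gene, fell by 1.00 while Col6a1 rose by 0.48 (limma adjusted p = 0.048 and 0.0499). These calls were lost in 14 and 17 of 22 alternatives. Il1a, not well above background on any B6.MRLc1 array, was at least 1.32-fold higher in B6 on the scale of the processed signal. Il1a was called in 0 of the 6 limma fits without 1 array, and with normexp it measured -0.00649 (adjusted p = 0.958).

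Camera called 12 of the 23 lists, 4 up and 8 down, and 7 without B6 array 1, without B6.MRLc1 array 1 or without B6.MRLc1 array 3. Among these 9 lists the calls were at adjusted p = 0.0437 for Sertoli cells, myoid cells and endothelium, 0.0362 for matrix, 0.0158 for adipocytes, 0.0187 for macrophages, 0.00742 for inflammation, 0.0187 for interferon response and 0.0116 for cell death. Under fry the cell death list was called (adjusted p = 0.0149) and the other 8 were not. Adjusted over the list alone, 4 inflammation genes fell and 1 rose, 3 cell death genes fell, 1 matrix gene rose and 1 fell, and 0 members passed in the other 6 lists. Members with the smallest p that did not pass included Gata4 (0.23) and Fshr (0.34) of Sertoli cells, Mylk (0.31) and Myl9 (0.16) of myoid cells, and Vwf (-0.20) and Tek (-0.23, and -0.10 with normexp) of endothelium. Cx3cr1 (0.79) and Cd163 (-0.70, and -0.17 with normexp) of macrophages, Tap1 (-0.58, and -0.29 with normexp) and Oas2 (-0.67) of the interferon response, and Fabp4 (1.15) and Cfd (1.04) of fat cells did not pass either. Cxcl1, a neutrophil chemokine gene, measured -2.05 (-1.36 with normexp; SE 0.41; adjusted p = 0.0663). Inflammation scores were 0.51, 0.27 and -0.30 on B6 arrays 1, 2 and 3 and -0.15, -0.14 and -0.16 on the B6.MRLc1 arrays. Adipocyte scores were lowest on B6 array 1 (-1.05) and highest on B6.MRLc1 array 2 (1.02).

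Of these 9 lists the cell death call alone held without any 1 array. Without B6 array 1 the calls of Sertoli cells and macrophages (camera adjusted p = 0.477), endothelium (0.145), inflammation (0.104) and interferon response (0.37) were lost. Without B6 array 2 those of endothelium (0.119), macrophages (0.0939) and interferon response (0.249) were lost, and without B6 array 3 those of myoid cells (0.175) and matrix (0.514). Without B6.MRLc1 array 1 the calls of Sertoli cells (0.113), myoid cells (0.317), interferon response (0.0969) and matrix (0.0927) were lost. Without B6.MRLc1 array 2 those of endothelium (0.109) and adipocytes (0.0566) were lost, and without B6.MRLc1 array 3 those of Sertoli cells (0.1), myoid cells (0.0831), endothelium (0.305), macrophages and interferon response (0.0516). Medians moved as well. Without B6 array 1 they were 0.00283 for Sertoli cells, -0.10 for macrophages, -0.17 for inflammation and -0.09 for interferon response, and the last was -0.08 without B6 array 2. Without B6 array 3 these lists had medians of 0.14, -0.40, -0.48 and -0.31. The endothelial median was -0.05 without B6.MRLc1 array 3, and the adipocyte median 0.63 without B6.MRLc1 array 2.

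**Figure D3:**
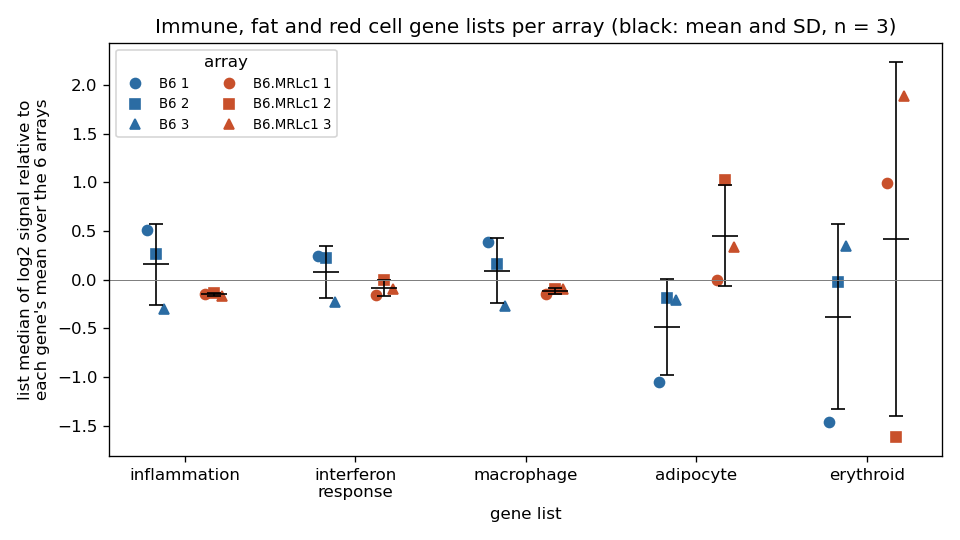
Scores of the immune, fat cell and red cell gene lists (vertical axis, log2 units relative to each gene's mean over the 6 arrays) for every array, with the mean and SD of 3 arrays per strain in black. On the inflammation list B6 arrays 1 and 2 sat at 0.51 and 0.27, above the other 4 arrays.

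Genes of mineral deposition were not called as a group by camera, which tests for a shift in 1 direction. The list holds both promoters and inhibitors of mineral deposition, so opposed changes can cancel in that test and in the median. Mgp, an inhibitor of calcification, was the only called gene among 35 tested members and fell 2.02-fold, from 5.65 ± 0.29 in B6 to 4.64 ± 0.09 in B6.MRLc1 (SD, n = 3; limma adjusted p = 0.0399). Spp1, which encodes osteopontin, measured -1.68 (SE 0.40; adjusted p = 0.0957), with 1 of 3 B6.MRLc1 arrays well above background, and -0.53 with normexp. Alpl, tissue-nonspecific alkaline phosphatase, measured 0.02 (SE 0.16; adjusted p = 0.957). Enpp1, which makes pyrophosphate, measured 0.24 (SE 0.32; adjusted p = 0.704), and its 2 probes differed in sign.

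The list's median was -0.0048 and its camera adjusted p was 0.597. Fry for change in either direction, which does not set members against other genes, gave adjusted p = 0.00357. Adjusted over the list alone, 4 members fell and 2 rose. Bmp7 measured -0.61 (adjusted p = 0.051). It was called in 5 of 22 alternatives, among them normexp (-0.62, limma adjusted p = 0.0228). Trpv6 measured -0.36 (adjusted p = 0.0937; -0.14 with normexp) and Ibsp, bone sialoprotein, 1.55 (adjusted p = 0.0893; 0.40 with normexp). Ibsp was well above background on 1 B6 and 2 B6.MRLc1 arrays. The Mgp call was lost in 8 of 22 alternatives. Among these were the fits without B6 array 1 or 2 and without B6.MRLc1 array 1, 2 or 3, at adjusted p = 0.1, 0.131, 0.102, 0.112 and 0.102 in that order. The log2 value of Mgp ran from -1.17 to -0.88 over the alternatives.

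The remaining lists were not called by camera. Fry for change in either direction, which does not set members against other genes, gave adjusted p from 5.98e-05 to 0.011 in these lists. The exception was the lymphocyte and granulocyte list (0.361). Camera adjusted p was 0.94 for the interval list, for 20 Leydig cell genes and for 30 oxidative stress genes, and 0.634 for 30 heat shock genes. It was 0.97 for 19 lymphocyte and granulocyte genes, 24 blood-testis barrier genes and 7 red cell genes, 0.172 for 19 retinoid genes and 0.573 for 8 epididymis genes. Called members were Crabp1 of the retinoid list (-0.72), Nectin3 of the barrier list (-0.52, and -0.30 with normexp), Spink8 of the epididymis list (-1.35) and Alas2 of the red cell list (-1.04). Pvrl3, the older symbol of Nectin3, was tested as a separate barrier member and measured only -0.06 (-0.02 with normexp). Adjusted over the list alone, 2 Leydig cell genes rose, 1 retinoid gene rose and 2 fell, 1 gene fell in the spermatogonium, barrier, epididymis and red cell lists, and 0 passed in the other 3. Medians were 0.02 for interval and heat shock genes, 0.02 for Leydig cells, 0.01 for oxidative stress and for the barrier, 0.10 for lymphocytes and granulocytes, -0.08 for retinoid, 0.27 for epididymis and 0.81 for red cell genes. The test and the median differed in sign for the interval and oxidative stress lists, and the mean differed in sign from the median for the interval, oxidative stress, barrier and lymphocyte and granulocyte lists. Under fry the interval, oxidative stress, barrier, epididymis and red cell lists had a downward direction against a median above 0.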

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

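Of the alternatives, only the one without both B6 array 1 and B6.MRLc1 array 2, which differed most in fat cell genes, was chosen after seeing the data. The 664 called genes became 50 without the filter on dim probes, 440 with the deposited series values, 1202 with a variance trend and 1607 with array weights. Leaving out 1 array in turn gave 50 to 486 genes, and leaving out both named arrays gave 0 by limma, with 3532 at an unadjusted p under 0.05. Fewer arrays were used there, and other causes were not tested. Deviations of same-number arrays correlated at -0.044, 0.172 and 0.0877. Numbers 2 and 3 exceeded all unlike pairs and 1 did not. The fit fixed beforehand had no pairing, and an effect of pairing or slide column is not excluded. The replicate (slide column) block gave 0 called genes by limma, with 4866 at an unadjusted p under 0.05, and 11 lists. With normexp 273 genes were higher and 612 lower. Normexp, quantile scaling and median centring moved the median of all genes by under 0.1. The interval odds ratio ran from 5.64 to 27.6 and kept its side of the threshold in the alternatives for which it was computed. It has no value with the replicate block or without both arrays, where no gene was called, and was not computed with the mean of a gene's probes. The 12 called lists became 7 to 10 without 1 array, 5 without both arrays, 2 with fry and 0 with an estimated correlation. The robust option does not exist for camera and was not run for lists. Slide and scan blocks were not run, since each had 1 level. The direction of the list test, camera or fry, turned against the reported camera direction in 40 of 482 list results, none of them called. The retinoid list was called with normexp, with array weights and without B6 array 3, and the red cell list without both named arrays. Signs below are those of list medians, a choice made after the results were seen.

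Signs of medians turned in 6 lists, 5 of them never called. The mineralization median was 0.0463 with normexp, 0.00626 with median centring, 0.0204 without the filter, 0.00172 above background on all arrays, 0.0189 with the floor and -0.0729 to 0.0112 without 1 array, above 0 only without B6 array 1. Leydig cell medians ran from -0.066 to 0.0775 without 1 array, with -0.0308, -0.032 and -0.0325 in 3 more fits below 0. Lymphocyte and granulocyte medians were -0.133 with array weights, -0.0847 to 0.193 without 1 array, and -0.0262 without both named arrays. The spermatocyte median was -0.113 to 0.0396 without 1 array, and not called where above 0. Oxidative stress measured -0.00841 with quantile scaling and -0.0231 to 0.053 without 1 array. Blood-testis barrier measured -0.00554 with quantile scaling and -0.0168 to 0.0248 without 1 array. Among named genes, Nuf2 turned to 1.15 with the mean of its probes and Nsun7 to 0.39 above background on all arrays, where another probe was read. Alpl was -0.0237 with array weights and -0.141 to 0.147 without 1 array. Enpp1 was -0.124 to 0.443 without 1 array, -0.0463 without both named arrays and -0.0164 with the mean of its probes. The causes were not tested. Of the other results for named genes, 1472 kept their direction and side of the threshold, 405 lost the call and 27 gained one. Both the number of arrays and dim probes limit the precision, and fewer spots were above background in B6.MRLc1.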

Other observations

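Several genes outside the groups described so far kept their call in all 6 fits that left out 1 array, and were picked here after their values were seen. They include Vgf, a secreted neuropeptide precursor gene (-2.41, limma adjusted p = 0.00938), and Syt5, a synaptotagmin gene of vesicle release (-1.03, adjusted p = 0.00872). Vgf was well above background on 1 B6.MRLc1 array. Of the 27 such genes, 7 lay in the interval span.

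Hba-a2, a haemoglobin gene, differed widely between animals of one strain. It read 0.99, 2.51 and 2.90 on B6 arrays 1, 2 and 3 and 3.61, 0.95 and 4.45 on B6.MRLc1 arrays 1, 2 and 3 (difference 0.87, SE 1.00, limma adjusted p = 0.657). Alas2, the erythroid gene of haem synthesis, read 2.41 to 2.60 in B6 and 1.45 to 1.48 in B6.MRLc1. Ccl2, a monocyte chemokine gene, read 0.50, 0.12 and -1.71 on the B6 arrays and -1.76 to -1.40 on the B6.MRLc1 arrays.

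The tests on spike-ins, on the share of negative folds, on the odds ratio of higher interval genes and on other probes were chosen after the results were seen. For the lower spermatid genes, an effect of slide row or background is argued against by the spike-in RNAs, but only within the range they cover. Of these, 6 lay in the brightness range of the members' means over the 6 arrays and differed by at most -0.273. Some members read below that range in B6.MRLc1, such as Catsper1 at -7.08, and dimmer spike-ins differed by 0.0929 and 0.743. For members near background the size of the fall depends on the background handling, as the normexp medians show. Genes outside the lists with like mean brightness had a median of 0.00474, against -1.69 for the 69 list members. A smaller share of spermatid RNA in the B6.MRLc1 testes may account for the pattern, but the 94.2% of members with a negative fold largely restate it. Fewer spermatids, less RNA per spermatid and a strain difference before heat stay open and were not tested.

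For the excess of interval genes, MRL sequence variants under the probes are a candidate explanation of lower signal. The excess of higher genes, with an odds ratio of 21.2, argues against variants and against a smaller share of spermatid RNA as the source of the higher genes only. Whether a smaller share of spermatid RNA accounts for the lower interval genes, which include Spata46, was not tested and stays open. For the lower genes the variants cannot be told apart from lower expression, because only 7 had another probe, and in 57.1% of these all other probes fell by at least 0.5 of the fold. Regulatory differences in the MRL segment remain an untested biological explanation.

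With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave the largest result. The real split called 664 genes and the highest of the others 0, by limma, with 445 to 2394 genes at an unadjusted p under 0.05 in those splits. The interval odds ratio was 7.64 in the real split, and no other split called a gene, so the highest other value is set at 0. For lists called by camera the real split gave 12 and the highest other 11. The elongating spermatid median was -1.88 in the real split (camera adjusted p = 6.79e-19) and reached -1.50 in another, which set B6 arrays 1 and 2 with B6.MRLc1 array 3 against the rest (adjusted p = 1.73e-16). The round spermatid median was -1.41 in the real split and reached -0.77 in that one (adjusted p = 1.75e-05), and the smallest adjusted p of the other splits was 8.58e-08.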
